A study of Mus musculus with 22 samples.

How the data were processed

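RNA was measured in arterial smooth muscle cells sorted from 7 mouse tissues, with 3 libraries each from aorta, heart, lung, kidney, bladder and stomach and 4 from intestine. Per the labels' protocols, recombinase activity was induced with tamoxifen at 0.75 mg per 10 g body weight for 3 days, RNA was isolated with a micro-scale column kit, and at most 10 ng of total RNA entered SMART-Seq v4, a full-length cDNA kit for very small inputs. The labels give a Cspg4-Dre/Acta2-CreERT/R26-GFP genotype, except for heart, where the Dre carries the inducible ERT part, so heart and its genotype cannot be separated. Groups were taken from the tissue labels.

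Per the submitters' processing notes, which give no order or role, the tools named were Trimmomatic 0.39, STAR 2.7.10a, Picard 3.0.0, featureCounts 2.0.4, DESeq2 1.36.0 and DESeq, with the genome build mm39. The authors deposited 1 table of 28099 genes in 22 columns, whose values are a signal: whole numbers that had been scaled per library, as judged from the values. In the 6 libraries where 1 read is worth more than 1 unit, between 99.82% and 100.0% of values lay on whole multiples of a fixed step, within rounding. Chance would give 10.6% to 30.3% in the aorta libraries and heart 3 but 74.5% in bladder 3 and 88.2% in kidney 3, where the share says less. The step was found for each library by a likelihood search from 0.3 to 12 over values of 15 to 1500, and dividing by it gave rebuilt reads. On simulated data with 50 random steps the search was wrong by over 1% in 2, both with a true step within 0.02 of 1; the lowest value of 15 was set after an earlier version failed such a test. Bladder 2, at 0.988, lies near that weak region, so its rebuilt depth is less certain. The table held no gene of the mitochondrial chromosome, so the list of mitochondrially encoded genes could not be tested, and 12 symbols were shared by more than 1 gene.

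A signal of 1 read ranged from 0.4216 in intestine 3 to 9.4205 in aorta 1. Rebuilt depth was 629456, 1540366 and 1927765 reads in aorta 1, 2 and 3 and 817157 in heart 3. In the other 18 libraries it lay between 4389363 and 12708394. Reads without molecular identifiers are not independent molecules, so floors and counting errors given here cover counting error only. Exonic lengths for reads per base came from GENCODE M21 (GRCm38), matched by gene identifier for 96.2% of genes; its coordinates were not used. Of 16601 tested genes with a length, 2782 reached 0.5 reads per exonic base in some library and are called near the read ceiling. Where reads are held at such a level, as for Myl9, the signal of a gene follows what 1 read is worth in a library rather than its abundance, so levels and fold changes of genes near the ceiling carry that limit. How the ceiling arose was not tested.

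The design had been written for counts. Because the deposited values are scaled signal, the alternative written there was used: limma-trend (limma 3.58.1, R 4.3.3) on log2(signal + 1), for 16917 genes with a signal of at least 10 in at least 3 libraries. Fold changes are on that scale and understate changes of low genes. All 22 libraries entered 1 fit with 7 tissue groups. Each tissue was set against the unweighted mean of the other 6, all 21 tissue pairs were compared, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. A gene restricted to a tissue passed in all 6 pairs with a log2 fold change of at least 1 in each. The labels do not say that libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

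Before the data were examined, 42 gene lists and the rule for named genes were fixed. For each tissue the rule took the 8 restricted genes with the largest log2 fold change and at least 10 CPM there. It also took the 8 largest among restricted genes that had at least 10 CPM in 4 of the other tissues, and the 6 most negative among genes lower in all 6 pairs. For each described list it took up to 4 members past the threshold and the 2 with the highest mean. Acta2 and Cspg4 were always named, and unnamed predicted genes were skipped. Some genes that the rule named are not reported here. Which lists to describe was chosen after their values were seen. Members were counted from limma, over all genes and over the list alone. Lists were tested with limma's camera at a preset correlation of 0.01, in 287 tests, again with an estimated correlation, and with fry.

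The limma script was tested on simulated counts at the real depths. In each contrast 200 genes of higher mean signal were changed, some 2-fold and the others 8-fold. Unlike these data, the simulation had 1 spread for all libraries and no read ceiling, so its false calls need not match those in aorta. At 8-fold the script recovered between 99% and 100%, and at 2-fold between 5% and 14%. As restricted genes it recovered 72% to 81% at 8-fold and 0% at 2-fold. It called 161 of 15869 unchanged genes lower in aorta, 30 of 15850 in heart and at most 14 in any other tissue. Alternatives covered scaling, pseudocount, filters, other tests (edgeR 4.0.16, DESeq2 1.42.0 and voom on rebuilt reads), a replicate block and each library left out. Those added after the data were seen were TMM scaling, array weights, edgeR on rebuilt reads, genes under the read ceiling, reads thinned to 629456 per library with edgeR, and fits without aorta or without aorta and heart 3. The edgeR test on thinned reads covered only 13445 genes under the read ceiling. The limma fit was also repeated on all 16917 genes with thinned reads scaled back to each library's signal total. Tables were prepared with Python 3.11.15 and numpy 2.4.6.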

Results

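The series compared arterial smooth muscle cells across 7 tissues in 22 libraries and named no reference tissue. Values below are deposited signal as mean ± SD over 3 libraries, or 4 for intestine, and log2 fold changes are given with the limma standard error. Acta2, which encodes smooth muscle alpha-actin and drives 1 recombinase of the sort (ENSMUSG00000035783, mm39 chromosome 19, 34218490 to 34232990), was above 0 in all 22 libraries. It was at 15687 ± 8106 in aorta, 2798 ± 436 in lung and 1497 ± 200 in intestine. The heart value of 8680 ± 9727 rested on heart 3, at 19908 from 2461 rebuilt reads, against 3309 and 2822 in heart 1 and 2. Cspg4, the pericyte and mural cell proteoglycan NG2 whose locus drives the other recombinase (ENSMUSG00000032911, chromosome 9, 56772317 to 56807154), passed in no tissue. Its mean ran from 322 ± 131 in lung to 1643 ± 1371 in kidney. Single libraries differed widely: Cspg4 was at 65 in kidney 2 against 2321 and 2542 in kidney 1 and 3. In bladder 3 it was at 15, from 11 rebuilt reads. Bladder 3 also had the lowest signal of all libraries for Myh11, at 1379, and Tagln, at 127. Of 35 contractile genes, 26 were near a read ceiling. Myl9 held 1885 to 2298 rebuilt reads in every library, a 1.22-fold range, while its signal ran from 934 to 19491; the reads of Tagln ranged 5.83-fold and those of Myh11 13.0-fold.

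**Figure D1:**
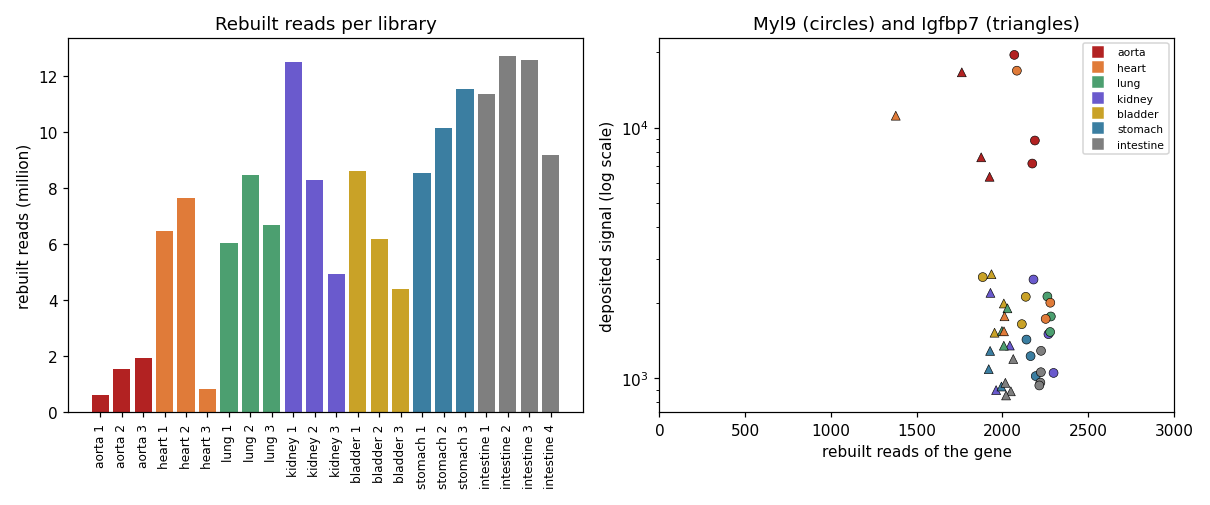
Left, rebuilt reads per library, 1 bar per library coloured by tissue. Aorta 1 to 3 and heart 3 lie at or under 1927765 reads and the other 18 at or above 4389363. Right, signal on a log axis against rebuilt reads for Myl9 (circles) and Igfbp7 (triangles), 1 point per library; Myl9 reads span 1.22-fold and its signal 20.9-fold.

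Across tissues, 10087 of 16917 genes (59.6%) differed in the limma F test. Tissue pairs differed in a median of 2906 genes, fewest between stomach and intestine (1035) and most between aorta and intestine (8850). That order rests on the spread shared by all tissues. With each pair fitted alone, stomach and intestine differed in 5504 genes and lung and intestine in 9750. Aorta and heart then differed in 0 genes in limma, against 3264 in the joint fit, with 1916 genes at an unadjusted p under 0.05. Within a tissue the median correlation between libraries, across genes, was 0.977 in stomach and 0.971 in intestine but 0.752 in aorta, and 19 of 22 libraries lay nearest to their own tissue; the other 3 were the aorta libraries. On the 500 most variable genes 21 did, all but aorta 3. In all, 1003 genes were restricted to 1 tissue, from 30 in heart to 248 in stomach. Of 287 list tests, 130 passed with the preset correlation and 29 with an estimated one, and other splits of the same libraries gave up to 114, so list members are counted beside each test.

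**Figure D2:**
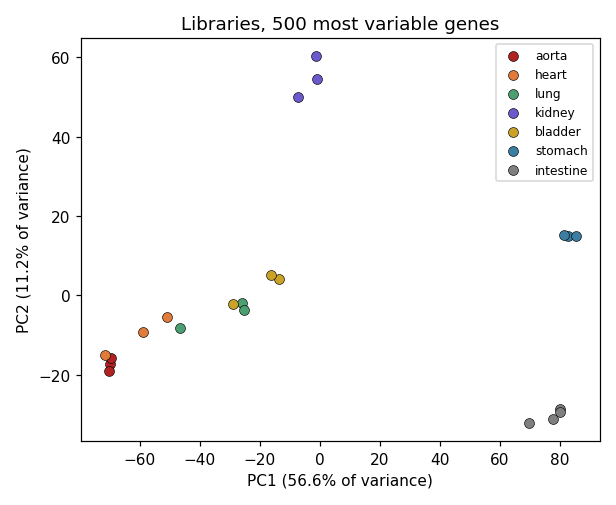
Principal components 1 and 2 of the 500 most variable genes, 1 point per library coloured by tissue. Component 1 held 56.6% of the variance and component 2 held 11.2%; stomach and intestine lie at high component 1 and kidney at high component 2.

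Hox genes, which record position along the body axis, separated the tissues. Posterior Hox genes were higher in bladder (11 of 12 members) and in kidney (10 higher and 1 lower), with the same counts adjusted over the list alone. Camera passed in both, with adjusted p = 0.00116 and 0.00124 with an estimated correlation. Hoxa13, the most distal HoxA gene (ENSMUSG00000038203, chromosome 6, 52234674 to 52237788), reached 481 ± 153 in bladder and at most 3.0 elsewhere. Hoxa10 was at 1012 ± 135 in bladder and 928 ± 162 in kidney, and Hoxa9 at 523 ± 56.5 in kidney. Anterior Hox genes fell in heart (15 of 19, 15 adjusted over the list alone, adjusted p = 0.000391 with an estimated correlation). In bladder 11 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.00116 with an estimated correlation). Hoxb7 was listed at 0 in all 3 heart libraries. In lung 8 anterior members rose and 2 fell (12 and 4 adjusted over the list alone, adjusted p = 0.0826 with an estimated correlation), led by Hoxb5 at 626 ± 32.2, while Hoxc6 and Hoxd8 fell there to 0.7 each.

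**Figure D3:**
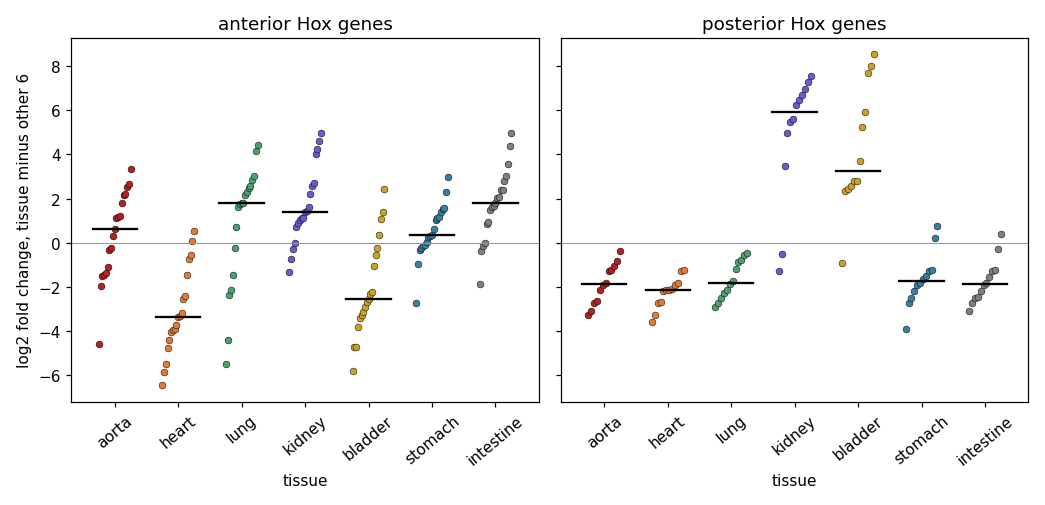
Log2 fold change of each anterior (left) and posterior (right) Hox gene, tissue minus the mean of the other 6, 1 point per gene with the median as a bar. The posterior medians lie above 0 in kidney and bladder alone, and the anterior medians below 0 in heart and bladder alone.

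In limma on signal, aorta had the largest count of differing genes, 8783, of which 1548 were higher and 7235 lower, and the median over all genes was -1.04. The gene most restricted to aorta was Ppef1, a calcium-binding serine/threonine phosphatase (ENSMUSG00000062168, chromosome X, 159406090 to 159518761), at 554 ± 226 against at most 44.0 elsewhere. Trim58, Pax1, Ibsp, Vstm2b and Or2t43 followed, with log2 fold changes between 5.56 and 6.05. Myl1, a skeletal muscle light chain, was also restricted and ran from 188 to 2579 between the aorta libraries. Among genes also expressed elsewhere, Ccn3, a matricellular protein (ENSMUSG00000037362, chromosome 15, 54609098 to 54617435), rose by 3.71 ± 0.18 (limma adjusted p = 7.51e-11) to 14420 ± 3683. Nox4, a hydrogen peroxide-producing oxidase, rose by 3.54 ± 0.31 to 2312 ± 1017. Efhd1, Emb, Cbr2, Ccdc3, Cpe and the small nuclear RNA Rn7sk also led. Of the 116 genes restricted to aorta, 80 were near the read ceiling, and with genes under it alone 33 were restricted. Eln, encoding elastin, rose by 1.95 ± 0.29 to 13366 ± 2515, although 8 of the 21 elastic fibre genes fell and 6 rose (8 and 6 adjusted over the list alone, 15 near the ceiling). Their median was -0.61 while camera leaned upward without passing (adjusted p = 0.143). Camera sets a list against the other tested genes, and the median over all genes here was -1.04. An upward lean of a list in aorta therefore need not mean a rise. Of all 16917 tested genes 7235 were lower, which bears on each count of fallen members in aorta. Proteoglycan and matricellular genes rose in 13 and fell in 7 of 30 (13 and 7 adjusted over the list alone, 23 near the ceiling, adjusted p = 0.0578 with an estimated correlation), with Ccn1 at 12802 ± 4989. Ccn3, Eln and Ccn1 were near the read ceiling and Nox4 was not. Anterior Hox genes rose in 5 and fell in 4 of 19 (4 and 3 adjusted over the list alone, adjusted p = 0.0228 with an estimated correlation), with Hoxa7 at 762 ± 239. Aldh1a2 and Aldh1a3, retinoic acid synthases, Eps8, Slc40a1 (the iron exporter ferroportin), B3gnt3 and AW112010 were listed at 0 in all 3 aorta libraries, where 3 reads would be worth 28.3, 12.2 and 9.9 signal.

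Contractile genes rose in 20 of 35 members and fell in 4 (20 and 4 adjusted over the list alone), with 26 near the read ceiling. The members under it had a median of -0.92, against -1.25 over all genes under it. Acta2 rose by 2.54 ± 0.38 (limma adjusted p = 3.86e-05), with 2655 to 3121 rebuilt reads per aorta library against 3087 to 3186 in intestine and 3489 to 3579 in lung. Itga8 rose by 2.91 ± 0.52 and Myh11 by 1.13 ± 0.38, a call that ended with array weights or without aorta 3. The transcriptional regulators Myocd, Srf and Mrtfb fell in limma on signal, but edgeR on rebuilt reads, voom and array weights called none of the 3, and without aorta 1 the calls of Myocd and Mrtfb ended. The camera call (adjusted p = 1.02e-13) had an adjusted p = 0.159 with an estimated correlation. Nuclear oxidative phosphorylation genes rose in 37 of 45 (38 adjusted over the list alone, 31 near the ceiling, adjusted p = 0.199 with an estimated correlation), including Cox6a1 and Cox4i1. Immediate early genes rose in 16 of 31 (16 adjusted over the list alone, 27 near the ceiling, adjusted p = 0.186 with an estimated correlation), including Fos and Dusp1. Fos held 2815 to 3847 rebuilt reads per aorta library against 4014 to 4172 in intestine, so its higher signal followed the worth of 1 read. Interferon response genes fell in 29 of 37 and rose in 2 (30 and 2 adjusted over the list alone, adjusted p = 0.0437 with an estimated correlation): Ifih1 was listed at 0, and B2m rose. Endothelial markers fell in 14 of 18 (14 adjusted over the list alone, adjusted p = 0.346 with an estimated correlation), with Cdh5 at 3.0 ± 5.2. Skeletal muscle markers rose in 3 of 12 (2 adjusted over the list alone, adjusted p = 0.468 with an estimated correlation), and Acta1 ran from 122 to 9026 between the aorta libraries. With DESeq2 on rebuilt reads 6230 genes differed in aorta, 38.7% of them higher against 17.6% in limma. With edgeR 4853 did, 46.5% of them higher, and among genes under the read ceiling 3239 did, 47.6% of them higher. With edgeR on thinned reads of genes under the ceiling 2775 did, 48.0% of them higher. The limma fit on thinned reads of all tested genes gave 1280 higher and 5010 lower. Array weights left 2200 and voom 1485, of which 907 were higher and 578 lower, the smallest count of the 7 tissues in both, and edgeR called more genes in intestine, 5006.

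In heart, 1020 genes were higher and 2093 lower. The most restricted was Comp, a cartilage and tendon matrix protein (ENSMUSG00000031849, chromosome 8, 70826208 to 70834716), at 2127 ± 638 against at most 118 elsewhere. It was followed by Myl2, Cyp26a1 (a retinoic acid-degrading enzyme), Prg4 (lubricin), Tlx1, Uts2r (the urotensin receptor), Clec3a and Trpv1 (the capsaicin receptor). Steap4, a metalloreductase and pericyte marker (ENSMUSG00000012428, chromosome 5, 8010457 to 8032213), rose by 3.46 ± 0.45 (limma adjusted p = 4.01e-05) to 3170 ± 364; Oxnad1, Zfpm2, Rdh5 and Nfkbil1 were also restricted. Edn3, Foxq1 and Hoxb7 were listed at 0 in all 3 heart libraries, and Igsf9 and Cpb1 had means of 2.7 or less.

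Pericyte markers rose in 12 of 18 (13 with 1 lower adjusted over the list alone, 14 near the ceiling), including Higd1b and Rgs5, and the camera call had an adjusted p = 0.0937 with an estimated correlation. Cardiomyocyte markers rose in 11 of 18 (15 with 1 lower adjusted over the list alone, adjusted p = 0.027 with an estimated correlation): ventricular light chain Myl2 was at 284 ± 127 and Tnnt2 at 1471 ± 147. Endothelial markers rose in 8 and fell in 1 of 18 (14 and 1 adjusted over the list alone, adjusted p = 0.119 with an estimated correlation), with Cdh5 at 448 ± 295 and the fenestral protein gene Plvap lower at 150 ± 89.6. Notch pathway genes rose in 10 and fell in 1 of 22 (11 and 2 adjusted over the list alone, adjusted p = 0.106 with an estimated correlation), including the ligand Dll4. The call of Jag2 ended without any 1 heart library. Fibrillar collagens fell in 9 of 17 (10 with 1 higher adjusted over the list alone, 14 near the ceiling, adjusted p = 0.433 with an estimated correlation), led by Col6a3 and Col5a1. Cell cycle genes fell in 12 of 34 (16 adjusted over the list alone, adjusted p = 0.376 with an estimated correlation). Contractile genes rose in 10 of 35 (18 adjusted over the list alone, 26 near the ceiling and 3 of the 10 under it, adjusted p = 0.322 with an estimated correlation), and Myl9 was at 16858 in heart 3 against 1998 and 1722 in heart 1 and 2. Heart 3 had 817157 reads, and without it 1478 genes differed in place of 3113; without the aorta libraries 6501 did. With edgeR on rebuilt reads 69.2% of 1942 calls were higher, against 32.8% in limma.

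In lung, 750 genes were higher and 588 lower. Pnmt, the enzyme that makes adrenaline from noradrenaline (ENSMUSG00000038216, chromosome 11, 98277276 to 98279007), was at 375 ± 45.3 against at most 2.3 elsewhere, and Vsnl1, a neuronal calcium sensor, at 450 ± 155. The T-box factors of lung mesenchyme Tbx4 (ENSMUSG00000000094, chromosome 11, 85777248 to 85806923) and Tbx5 rose by 5.59 ± 0.84 and 6.10 ± 0.98 (limma adjusted p = 0.000265 and 0.000525). Among genes expressed in most tissues, Nr1h3 (the sterol receptor LXR alpha), Niban1, Fbxw17, Mettl7a1, Tstd3 and Socs2 were restricted to lung, with log2 fold changes of 1.68 to 2.22. Avpr1a, the vasopressin receptor of vascular smooth muscle, fell to 0.7 ± 0.6 against 2169 in bladder, and Frzb, Rergl, Scn4b, Or51e1 and Kcnk1 were also lowest there.

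Lung epithelium markers rose in 13 of 16 (14 adjusted over the list alone, adjusted p = 0.00116 with an estimated correlation), including the surfactant genes Sftpa1 at 1714 ± 506 and Sftpc at 1240 ± 151 and the club cell gene Scgb1a1 at 250 ± 110. Visceral smooth muscle markers rose in 5 and fell in 2 of 12 (7 and 2 adjusted over the list alone, adjusted p = 0.127 with an estimated correlation): Lgr6 and the muscarinic receptor Chrm2 rose, and the fall of Nkx2-3 ended without any 1 lung, stomach or intestine library. Basement membrane genes fell in 4 of 22 (6 adjusted over the list alone, adjusted p = 0.346 with an estimated correlation), namely Nid1, Col4a2, Col4a1 and Lamc1, the last not without any 1 lung library. Calcium handling genes fell in 8 and rose in 2 of 41 (10 and 3 adjusted over the list alone, adjusted p = 0.362 with an estimated correlation), with Pln, the inhibitor of the sarcoplasmic calcium pump, at 21.3 ± 6.7 and Piezo1, a stretch-activated channel, at 32.3 ± 5.7. Of the differing genes 56.1% were higher, but 45.0% with median-of-ratios scaling, 40.6% with DESeq2 and 45.7% without the aorta libraries. The share was 80.0% with no filter, 64.5% with voom and 68.5% with edgeR on rebuilt reads. With edgeR on thinned reads of genes under the ceiling it was 71.6%, but the limma fit on thinned reads gave 499 higher and 517 lower. The count of 1338 became 570 to 652 without a lung library, 2087 without aorta 1 and 4388 without the aorta libraries.

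In kidney, 1075 genes were higher and 696 lower. Ren1, encoding renin (ENSMUSG00000070645, chromosome 1, 133278248 to 133288063), was at 2205 ± 1023 against at most 243 elsewhere, a log2 fold change of 8.00 ± 1.18 (limma adjusted p = 0.000104). Of 9 renin cell and mesangial markers, 6 rose (7 adjusted over the list alone, 7 near the ceiling, adjusted p = 0.0207 with an estimated correlation), including Akr1b7, Gata3 and Foxd1. Trpc1, a cation channel, and Crim1 were restricted among widely expressed genes. Foxf1, a mesenchymal factor of gut and lung, fell to 59.0 ± 25.2 against 3081 in bladder, and Glipr1, Myrf, Trnp1, Steap3 and Sync were also lowest.

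Visceral smooth muscle markers fell in 7 and rose in 1 of 12 (7 and 1 adjusted over the list alone, adjusted p = 0.00816 with an estimated correlation), including Foxf2, Hand2 and Actg2, the enteric actin, at 312 ± 102. Vasoactive receptors rose in 18 and fell in 6 of 63 (25 and 6 adjusted over the list alone, adjusted p = 0.468 with an estimated correlation), among them the adrenergic receptor Adra1a and the dopamine receptor Drd1, while the kinin receptor Bdkrb1 fell. Notch pathway genes rose in 6 of 22 (11 adjusted over the list alone, adjusted p = 0.149 with an estimated correlation), with Notch3 at 4328 ± 2679, whose call ended without kidney 1 or kidney 3 and without the aorta libraries. Elastic fibre genes fell in 5 of 21 (6 adjusted over the list alone, 15 near the ceiling, adjusted p = 0.257 with an estimated correlation). Nephron markers rose in 19 of 20 (19 adjusted over the list alone, adjusted p = 5.17e-05 with an estimated correlation), with Slc34a1 of the proximal tubule at 1834 ± 561 and Umod and Slc12a1 of the thick ascending limb at 2075 ± 1256 and 2388 ± 2728. Slc14a2, Acsm2, Calb1 and Miox were likewise restricted. Without kidney 1 or kidney 3 the count of 1771 became 909 and 884. Without aorta and heart 3, 1691 genes were higher and 1902 lower, and with edgeR on rebuilt reads 1797 and 401.

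In bladder, 1406 genes were higher and 1252 lower. Beside Hoxa13 and Hoxa11, the genes most restricted to bladder were Wnt2, a secreted growth signal (ENSMUSG00000010797, chromosome 6, 17988939 to 18030584), at 2102 ± 389 against at most 40.7 elsewhere, and Adam23 at 2179 ± 530. With them came Cntn4, the melanocortin receptor Mc5r, the urea transporter Slc14a1 and Krtdap. Widely expressed genes restricted to bladder included Thbs2, an anti-angiogenic matrix protein, at 9308 ± 671 (limma log2 fold change 3.53 ± 0.34, adjusted p = 1.26e-06), Dnm1, Apod, Scd1, Dab2, Gfpt2, Cpxm1 and Matn2. Edn1, encoding the vasoconstrictor endothelin-1, fell to 14.0 ± 14.1, and Hoxb2, Ddo, Mecom, Kcnh2 and Gipc2 were also lowest there.

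Fibrillar collagens rose in 10 and fell in 1 of 17 (14 and 1 adjusted over the list alone, 14 near the ceiling, adjusted p = 0.17 with an estimated correlation), with Col12a1 at 3564 ± 1456. Elastic fibre genes rose in 12 of 21 (13 adjusted over the list alone, 15 near the ceiling, adjusted p = 0.119 with an estimated correlation). Fibroblast markers rose in 11 of 19 (15 adjusted over the list alone, all 19 near the ceiling, adjusted p = 0.268 with an estimated correlation), including Pdgfra and Pi16. Wnt pathway genes rose in 16 and fell in 4 of 45 (19 and 5 adjusted over the list alone, adjusted p = 0.225 with an estimated correlation), including Notum, Dkk2 and Lef1. Inflammatory genes rose in 17 and fell in 1 of 36 (20 and 2 adjusted over the list alone, 19 near the ceiling, adjusted p = 0.0295 with an estimated correlation), including Ptges and Il11. In the same libraries immune cell markers rose in 13 of 17 (16 adjusted over the list alone, adjusted p = 0.0489 with an estimated correlation), with the complement genes C1qa, C1qb and C1qc at 298 to 570. Mesothelial markers rose in 7 of 10 (8 adjusted over the list alone, adjusted p = 0.215 with an estimated correlation). Urothelial markers rose in 6 of 13 (8 adjusted over the list alone, 9 near the ceiling, adjusted p = 0.186 with an estimated correlation), Upk1a running from 79 to 1957. Without bladder 2 or bladder 3 the count of 2658 became 1759 and 1661, and without the aorta libraries it became 4212, with 1849 higher and 2363 lower. With library totals scaling 1144 genes were higher and 1441 lower, with ribosomal protein genes left out 1143 and 1437, and with edgeR 2103 and 704.

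In stomach, 2275 genes were higher and 1172 lower. Barx1, a homeobox factor of stomach mesenchyme (ENSMUSG00000021381, chromosome 13, 48816474 to 48819983), rose by 8.25 ± 0.73 (limma adjusted p = 9.46e-08) to 986 ± 96.8, and Gata4, Pitx1 and Foxq1 rose with it. Npy1r, the vasoconstrictor neuropeptide Y receptor, fell by 3.30 to 97.0 ± 18.5, the potassium channel subunit Kcnab1 by 2.87 to 122 ± 8.7, and Gdf10, Cd200, Ntf3 and Or5m3b were also lowest in stomach. Cell cycle genes rose in 27 of 34 (31 adjusted over the list alone, adjusted p = 0.0937 with an estimated correlation), with Top2a at 733 ± 177 and Mki67 at 564 ± 61.8.

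Gastric epithelium markers rose in 14 of 14 (14 adjusted over the list alone, 12 near the ceiling, adjusted p = 0.00208 with an estimated correlation). The surface mucin gene Muc5ac (ENSMUSG00000037974, chromosome 7, 141342709 to 141372968) was at 3736 ± 511 and the proton pump gene Atp4a at 4124 ± 691, and Gsdma2, Cblif, Bpifb1, Mucl3, Pga5 and Vsig1 completed the restricted genes. B3gnt3, Gpt2, Hid1, Pcx, Hip1r, Akr1c14, Ptgr1 and Ica1 were restricted among genes expressed more widely. Intestinal epithelium markers rose in 13 and fell in 7 of 24 (14 and 7 adjusted over the list alone, 17 near the ceiling, adjusted p = 0.35 with an estimated correlation). Skeletal muscle markers rose in 4 of 12 (8 adjusted over the list alone, adjusted p = 0.646 with an estimated correlation), including Myh1 at 79.7 ± 18.9, whose call ended without any 1 stomach library. Contractile genes fell in 12 of 35 (18 adjusted over the list alone, 26 near the ceiling, adjusted p = 0.373 with an estimated correlation). Immediate early genes fell in 14 of 31 (17 adjusted over the list alone, 27 near the ceiling, adjusted p = 0.186 with an estimated correlation), led by Gadd45b and Maff. Leaving out any 1 stomach library lowered the 3447 calls to between 1932 and 2126, and array weights raised them to 9460.

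In intestine, 2620 genes were higher and 1686 lower. Nkx2-3, a homeobox factor of gut mesenchyme (ENSMUSG00000044220, chromosome 19, 43600764 to 43604331), rose by 8.42 ± 0.87 (limma adjusted p = 5.49e-07) to 1806 ± 233. Of 12 visceral smooth muscle markers 8 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 0.0578 with an estimated correlation), including Foxf2, Chrm2 and Pcp4. Actg2 was at 1190 ± 173 and did not pass. Gja1, the gap junction gene connexin 43, and Cpb1 were restricted among genes that had at least 10 CPM in 4 of the other tissues. Sfrp2, a secreted Wnt modulator (ENSMUSG00000027996, chromosome 3, 83673628 to 83681623), fell to 5.0 ± 3.6 against 2542 in aorta, and Itgbl1, Cbr2, Pcolce2, Ccn5 and Pi16 were also lowest. Inflammatory genes rose in 17 and fell in 2 of 36 (18 and 2 adjusted over the list alone, 19 near the ceiling, adjusted p = 0.293 with an estimated correlation), with the neutrophil chemokine Cxcl5 at 340 ± 69.1.

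Intestinal epithelium markers rose in 23 of 24 (23 adjusted over the list alone, 17 near the ceiling, adjusted p = 0.000312 with an estimated correlation). Cdh17, an intestinal cadherin (ENSMUSG00000028217, chromosome 4, 11758147 to 11817895), was at 1229 ± 350, Cdx1 at 674 ± 233 and Reg3b at 632 ± 85.2, and Cps1, Fcgbp, Clca3b and the pancreatic enzyme genes Pnlip and Prss2 were also restricted. Gastric markers rose in 8 and fell in 1 of 14 (8 and 1 adjusted over the list alone, 12 near the ceiling, adjusted p = 0.365 with an estimated correlation). Cell cycle genes rose in 20 of 34 (27 adjusted over the list alone, adjusted p = 0.204 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 40 of 45 (44 adjusted over the list alone, 31 near the ceiling, adjusted p = 0.338 with an estimated correlation). Immediate early genes fell in 26 of 31 (28 adjusted over the list alone, 27 near the ceiling, adjusted p = 0.0668 with an estimated correlation), led by Egr2 and Nr4a2. Contractile genes fell in 18 of 35 (21 adjusted over the list alone, 26 near the ceiling, adjusted p = 0.41 with an estimated correlation). Acta2 fell by 1.28 ± 0.34 (limma adjusted p = 0.0083), a call that ended when the aorta libraries were left out, as did those of Myl9, Fos, Cox4i1 and Cox6a1. Array weights raised the 4306 calls to 10102, and genes under the read ceiling gave 2741.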

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

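In intestine, the only group with 4 libraries, 68 sets of values were checked for a library far from the others, and 5 had one, of which 4 are given here. Chance gives about 1 in 20. Kif11, a mitotic kinesin, was at 312 in intestine 3 and between 153 and 179 in the other libraries. Nfkbia was at 1058 in intestine 4 and between 808 and 850 elsewhere. Pcolce2 was at 38 in intestine 1 against 19 to 21, and Itgbl1 at 27 in intestine 1 against 9 to 11.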

How the results depend on the processing

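Counts of differing genes, given as count and tissue, moved by over 1.5 times under the settings below, and the cause was not tested unless fewer genes or libraries entered. Those chosen after the data were seen were TMM scaling, array weights, the read ceiling and thinning settings, edgeR and the fits without aorta. A pseudocount of 0.1 gave 871 (lung), with restricted counts of 13 (heart), 33 (lung), 122 (kidney), 64 (bladder), 96 (stomach) and 146 (intestine). A pseudocount of 5 gave 2028 (lung), with restricted counts of 63 (heart), 213 (bladder) and 407 (stomach). No filter on low values gave 3347 (lung), with restricted counts of 578 (lung). Lung 2 and 3 held 24469 and 25608 genes above 0, against 18331 in lung 1 and at most 20827 in a library of another tissue. A filter of 5 CPM in 3 libraries gave restricted counts of 36 (lung) and 118 (kidney). Array weights gave 2200 (aorta), 4783 (lung), 3793 (kidney), 9460 (stomach), 10102 (intestine) and 4886 (median pair), with restricted counts of 55 (aorta) and 554 (stomach). Genes under the read ceiling gave 755 (lung), 1114 (kidney), 1682 (bladder), 2741 (intestine), 1845 (median pair) and 81 (list tests), with restricted counts of 33 (aorta). DESeq2 on rebuilt reads gave 3151 (lung), 3059 (kidney) and 5221 (stomach), with restricted counts of 49 (heart), 32 (lung) and 123 (kidney). Voom on rebuilt reads gave 1485 (aorta), 1896 (heart), 5500 (lung), 3788 (kidney), 9596 (stomach), 10166 (intestine) and 4796 (median pair), with restricted counts of 187 (aorta), 49 (heart) and 590 (stomach). EdgeR on rebuilt reads gave 4853 (aorta) and 1942 (heart), with restricted counts of 26 (lung). EdgeR on genes under the ceiling gave 3239 (aorta), 1270 (heart) and 1750 (median pair), with restricted counts of 37 (aorta), 18 (heart), 18 (lung), 102 (kidney), 76 (bladder), 105 (stomach) and 104 (intestine). EdgeR on thinned reads, also of genes under the ceiling alone, gave 6120 (any tissue), 2775 (aorta), 865 (heart), 814 (lung), 1442 (bladder), 2545 (intestine) and 1160 (median pair), with restricted counts of 44 (aorta), 16 (heart), 13 (lung), 66 (kidney), 61 (bladder), 109 (stomach) and 69 (intestine). Leaving out heart gave 2348 (lung), with restricted counts of 253 (aorta). Leaving out aorta and heart 3 gave 6083 (lung), 3593 (kidney), 5923 (bladder), 5530 (stomach) and 5035 (median pair), with restricted counts of 72 (heart), 147 (lung), 248 (bladder) and 429 (stomach). Leaving out aorta gave 6501 (heart), 4388 (lung) and 4212 (bladder), with restricted counts of 87 (heart), 138 (lung) and 192 (bladder). An estimated correlation gave 29 (list tests). Leaving out each library in turn gave 9131 to 11510 (any tissue), 6894 to 9805 (aorta), 1478 to 3951 (heart), 570 to 2087 (lung), 884 to 2472 (kidney), 1661 to 3412 (bladder), 1932 to 4516 (stomach), 2955 to 5490 (intestine), 2166 to 3455 (median pair), 123 to 136 (list tests), and restricted counts of 68 to 218 (aorta), 21 to 46 (heart), 40 to 72 (lung), 165 to 193 (kidney), 87 to 142 (bladder), 168 to 274 (stomach), 214 to 252 (intestine). Heart 3 set the lowest heart count, and each lung and stomach library, kidney 1 and 3, and bladder 2 and 3 moved their own tissue by over 1.5 times. Same-numbered libraries had a median correlation of deviations of -0.010 over 63 pairs, 3 of them over 0.1. Their highest was 0.26, against 0.216 over 144 pairs with different numbers. Of 21 libraries 5 correlated best with their own number, so these values show no pairing by number. They do not exclude shared animals. With the replicate block 9093 genes differed in any tissue and 131 list tests passed, and no count moved by over 1.5 times. Scaling moved the median of all genes by over 0.1 in lung (0.15 to 0.02 with median-of-ratios), bladder (0.06 to -0.07 with library totals), intestine (0.34 to 0.45 with library totals) and aorta (-1.04 to -1.14 with ribosomal protein genes left out). Of 17984 values of named genes under alternatives, 17286 kept direction and side of the threshold, 463 lost the call, 174 gained it, 61 changed sign without a call in either fit and 0 reversed while called; of 4728 list values 4442 kept the call, 286 lost it and 0 reversed. Depth limits aorta and heart 3 most: 1 read there is worth between 3.3027 and 9.4205 signal.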

Other observations

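Developmental transcription factors, as a list of 95 tested genes, rose and fell in every tissue: 23 higher and 21 lower in heart, 24 and 9 in bladder, 21 and 23 in intestine, and 7 and 35 in aorta. Over all 16917 tested genes, the higher and lower counts were 1020 and 2093 in heart and 1406 and 1252 in bladder. They were 2620 and 1686 in intestine and 1548 and 7235 in aorta. Gata4, a cardiac and gastric factor, was at 997 ± 327 in heart and 2046 ± 225 in stomach and listed at 0 in aorta. Gata5 was at 1076 ± 279 in bladder and 658 ± 124 in lung and listed at 0 in aorta. Pitx1 was at 1104 ± 122 in bladder and 858 ± 70.5 in stomach, and Alx1 at 300 ± 110 in kidney against at most 6.0 elsewhere. Tbx5 was listed at 0 in all 4 intestine libraries. Nfib, a nuclear factor I gene, was between 1254 and 2909 in every tissue.

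The test of the number of lower calls in aorta with thinned reads and the test of own-organ markers were chosen after those values were seen, and the limma test with thinned reads after the edgeR values were. The first pattern is the rise of contractile genes in aorta and their fall in intestine, against a read ceiling together with the worth of 1 read. The 26 members near the ceiling had a median of 1.37 in aorta. That was above all 10000 random lists matched on reads per base in the other tissues (percentile 100, their middle 95% from 0.14 to 0.89). The test cannot decide, because reads near the ceiling no longer rank genes by abundance. Genes far above it can stay there in shallow libraries where matched genes drop under it. In intestine the median of the 26 members, -0.71, was at percentile 1.9, at the edge of the random lists (-0.71 to -0.37). The matching has the same limit there, so that test does not decide either. Genes of 1 cell type move together and random ones need not. The matched lists had a median of 0.50 in aorta and -0.55 in intestine, so part or all of both patterns may come from the ceiling. The contractile members under the ceiling had a median of -0.92 in aorta. All genes under it had one of -1.25 there, so that value shows no fall particular to contractile genes. A difference between the tissues stays open and was not tested further. Oxidative phosphorylation and immediate early genes, also mostly near the ceiling, were not tested against matched lists.

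The second pattern is the excess of lower genes in aorta, 82.4% of limma calls. Array weights kept it, with 17.1% of calls higher. Its size depended on the test used: 38.7% were higher with DESeq2 and 46.5% with edgeR on rebuilt reads. With voom 61.1% were, which turned it. With every library thinned once to equal reads and the same limma fit, 79.7% of 6290 calls were still lower. That argues against fewer reads alone as the whole cause. The thinned reads still carried the read ceiling, which thinning does not undo. Before thinning, 35 to 137 genes reached 0.5 reads per exonic base in the aorta libraries and 42 in heart 3, against 362 to 1765 in the others. A depth effect through the ceiling stays open. With edgeR on thinned reads of genes under the ceiling 1444 genes were lower, against at most 34 in 20 other splits thinned alike. But 1331 were higher, so that count does not bear on the excess. At equal reads the median number of genes with a read in aorta was 0.782 times that in the other tissues, heart 3 left out. The number in heart 3 was 0.822 times the mean of heart 1 and 2. Few molecules captured in these libraries would give such ratios, but so could reads held at the ceiling in the deeper libraries. Tissue and capture are confounded in aorta, and a difference of the tissue stays open.

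The third pattern is that markers of an organ's main cells were high in its own libraries. Over 50% of the list rose in its own organ for 5 of the 6 lists, from 61.1% for cardiomyocyte markers in heart to 100% for gastric markers in stomach, with 46.2% for urothelial markers in bladder. Urothelial markers rose in 53.8% of members in stomach and 30.8% in intestine. The count of lists would come out alike if the sorted cells expressed these genes, so that and RNA or cells of the surrounding organ cannot be told apart. Both stay open. Sorting on GFP would remove unlabelled cells, but how fully it did so was not measured.

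Drawing 100 splits of the 22 libraries, the real one included, 1 in 100 gave a count as large for each result below. That is the real split itself and the smallest share 100 splits can give. All labels were shuffled, so differences among tissues enter the spread of the other splits. The share bears on the labels as a whole and does not show that any 1 tissue stands out. It also treats libraries as independent, which the labels do not show. The margin was narrow in lung, where 570 to 652 genes differed without any 1 lung library, fewer than in the highest other split of all libraries. The real and highest other counts were 10087 and 152 for any tissue, and 2906 and 1 for the median pair. Against the mean of the other tissues they were 8783 and 2587 in aorta, 3113 and 799 in heart, 1338 and 1206 in lung, 1771 and 564 in kidney, 2658 and 226 in bladder, 3447 and 1708 in stomach, and 4306 and 1399 in intestine. For restricted genes they were 116 and 4 in aorta, 30 and 0 in heart, 64 and 0 in lung, 185 and 129 in kidney, 119 and 0 in bladder, 248 and 20 in stomach, and 241 and 0 in intestine. List tests gave 130 and 114, so the number of list calls says little beyond structure among the libraries.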
